A study of Coryphaena hippurus with 21 samples.

How the data were processed

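RNA sequencing libraries were made from pooled whole mahi-mahi larvae (Coryphaena hippurus) at 48 hours post fertilisation. The larvae had been kept in clean seawater or in dilutions of a HEWAF, an oil and seawater preparation that the labels name only by that abbreviation, of slick or source oil from the Deepwater Horizon spill. Libraries were directional, per the labels' protocols. The 21 deposited libraries fell into 7 groups, labelled as 3 replicates each: control, slick oil at 0.5%, 1% and 2%, and source oil at 0.125%, 0.25% and 0.5%. The labels do not say that each library came from its own beaker, so p-values measure only the spread between these libraries, which may be technical.

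Per the submitters' processing notes, Trimmomatic 0.33, Bowtie 1.1.1, RSEM and DESeq were used; the notes as held here give no role or order for these tools. The deposited values per library were RSEM expected counts, which need not be whole numbers, with contig lengths in bases, for 341414 transcripts in 258722 Trinity genes per the file headers and identifiers. A Trinity gene is a cluster of contigs assembled without a genome. The files do not pair these identifiers with gene names, and no genome was used here. The gene lists and the named marker that had been fixed before the data were examined could therefore not be tested, and contigs appear under their own identifiers. The authors' deposited tables held, for 6 exposed groups against control, a log2 fold change given as control over exposed, a p-value with its adjusted value, and a mean signal per transcript, all made by the authors. Signs from those tables were turned so that positive means higher in exposed larvae.

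The third file of the slick 1% group and the third file of the source 0.25% group held gene totals that differed from replicate 2 of the same group by at most 0.04 counts over 258722 genes, below any sampling noise. Each pair was counted as 1 library, which left 19 distinct libraries and n = 2 in these groups. Total counts ran from 26868206 to 128811410 over the 19 libraries, with a median of 53090239. Reads were not tagged with molecular identifiers as far as the labels say, so counting limits cover counting error only.

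Expected counts were summed over the transcripts of each Trinity gene and rounded to whole numbers. All 19 libraries entered 1 edgeR fit (edgeR 4.0.16, R 4.3.3) with a mean per group, TMM factors, filterByExpr with a minimum count of 10, and the quasi-likelihood test, with Benjamini-Hochberg adjustment over the 86459 genes kept and a threshold of 0.05. Dose trends were slopes on the nominal dilution in percent, fitted to control and the groups of 1 oil. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to the library total over the kept genes with TMM factors. A gene with no count in any control library has a fold given against a floor of 3 counts over the 3 control libraries together. Intervals of differences are 95% intervals from the same fit.

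The rule for genes to name, fixed before the data were examined, took genes past the threshold with a mean of at least 1 CPM in 1 of the groups and no overlap between libraries of the groups, ranked by log2 fold change. Its condition of a gene name could not be applied, and at most 2 identifiers per direction and comparison were kept. On simulated counts for 86459 genes, the fit of the high slick dose against control recovered 21% of genes changed 2-fold and 84% of genes changed 4-fold, with 2 false calls. For the middle slick dose, with 2 libraries, it recovered 13% and 69%. The changed genes were drawn from those above 1 CPM in controls, so recovery does not cover tested genes of lower level. Each gene was drawn on its own, without differences between whole libraries, so the false calls are no measure for the real libraries.

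Calls shared between exposures, and fold changes at the high doses, were set beside 20 simulations in which all 19 libraries, controls included, were drawn gene by gene from 1 mean per gene, so that the comparisons shared the error of the drawn controls. These held 0.25 calls on average, so the genes of smallest p per direction, as many as the real lists held, were compared instead of calls. The alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a stricter filter of 50 counts in 3 libraries, the replicate number as a block, transcripts in place of genes, only the groups compared in the fit, a log2 threshold of 1, dose ranks, and each library left out. For a gene with 1 transcript the refit on transcripts held the same counts, among 131441 tested features in place of 86459. Counting the repeated files as separate libraries and adding an axis score as a covariate were chosen after seeing the data. Principal components were taken from log2 CPM of 63533 genes with at least 20 counts in 3 libraries, with 100000 permutations of the group labels.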

Results

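The data described the messenger RNA of mahi-mahi larvae at 48 hours post fertilisation, after static exposure from the embryo stage to slick oil or source oil of the Deepwater Horizon spill. Control larvae (n = 3) were compared with larvae in slick oil at 0.5% (n = 3), 1% (n = 2) and 2% (n = 3), and in source oil at 0.125% (n = 3), 0.25% (n = 2) and 0.5% (n = 3). These are nominal dilutions of the oil preparation, called the low, middle and high dose of each oil here. The middle doses had n = 2 because the third file of each differed from replicate 2 by at most 0.04 counts per gene, below the sampling noise, and was counted as the same library. Control libraries held 47681606 to 69271086 counts. Slick libraries held 41516360 to 128811410 counts and source libraries 26868206 to 100386257 counts. The title of the series names dose-responsive profiles, so the doses of each oil were compared with control, with each other and between oils. The files do not pair their contig identifiers with gene names.

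A set of 37 genes was higher than control in all 6 exposures, and 1 gene was lower in all 6, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In 20 simulations of unchanged larvae with drawn controls in common, the higher genes of smallest p, in lists as long as the real ones, had 0.95 genes in common over all 6 on average, and at most 2. Each gene was drawn on its own there, without differences between whole libraries, so overlap from such differences in the controls is not covered. The gene lower in all 6, TRINITY_DN140104_c2_g1, stood at 16 ± 3 CPM in control larvae, 5.21 ± 0.657 at the high slick dose and 4.92 ± 0.769 at the high source dose (SD, n = 3 each). The 37 genes took 0.032% ± 0.00157 of the counts of tested genes, scaled with TMM factors, in control larvae (SD, n = 3). They took 0.214% ± 0.0451 at the low slick dose (SD, n = 3), 0.325% ± 0.0139 at the middle dose (SD, n = 2) and 0.325% ± 0.0286 at the high dose (SD, n = 3). In source oil the shares were 0.19% ± 0.0117 (SD, n = 3), 0.23% ± 0.021 (SD, n = 2) and 0.369% ± 0.0228 (SD, n = 3). In every exposed group most of the share came from 1 gene, the most abundant of the set. Its group means were 1240 to 2410 CPM in exposed larvae and 114 CPM in control larvae. The set was chosen for being higher in these libraries, so its levels are a description and not independent evidence. The 37 genes became 15, 14 and 16 without control replicate 1, 2 or 3, 19 and 21 without source_L replicate 1 or 2, 19 without source_M replicate 1, and 5 when each fit held only the groups compared. TRINITY_DN140104_c2_g1 was no longer called in all 6 without any 1 of the control, slick_L, source_L or source_M libraries or without slick_M replicate 2. The same held with the replicate number as a block, without a low-count filter and with only the groups compared in each fit. Where a left-out library ended its call, the log2 fold change was -0.9 to -1.48, against -1.06 to -1.36 for the low and middle doses in the full fit. On its main transcript alone it was called in no exposure, with log2 fold changes from -0.09 to -1.81 (edgeR adjusted p from 0.823 to 1). DESeq2 called 7 genes lower in all 6, TRINITY_DN140104_c2_g1 among them. The axis covariate, added after seeing the data, gave 40.

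The most abundant of the 37 genes, with a main contig of 4261 bases, stood at 114 ± 6.57 CPM in control larvae (SD, n = 3). It reached 1420 ± 340 CPM at the low slick dose (SD, n = 3) and 2410 ± 236 CPM at the high source dose (SD, n = 3). It was chosen for its abundance after its values were seen. The median log2 fold change of the set was 3.14, 3.62 and 4.08 at the low, middle and high slick doses, and 2.94, 3.41 and 3.51 at the source doses. These medians did not move when the 7 members without a count in any control were set at their bound. A further 3 members had 1 to 3 counts in all controls together. Within slick oil 22 of the 37 genes had a higher level at each dose step, and within source oil 25 did, where a random order of the doses gives 16.7% per gene; genes of the same libraries are not independent. In source oil the counts differed between parts of the set, a difference that was not tested. Of the 27 members with more than 3 control counts, 24 were higher at the high than the low source dose, by a median log2 difference of 0.96, and of the other 10 members 4 were, with a median of -0.18. In slick oil 26 of the 27 and 9 of the 10 were higher at the high dose.

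**Figure D1:**
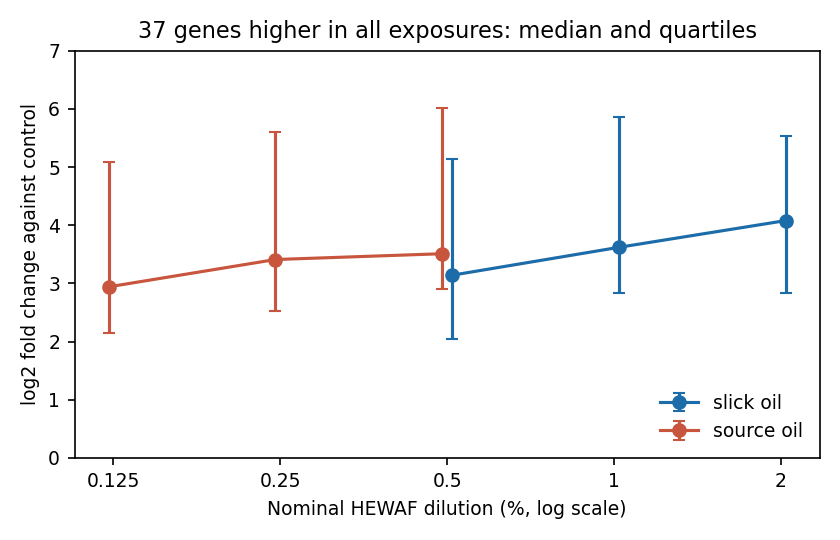
Log2 fold change against control (y axis) of the 37 genes higher in all exposures, by nominal dilution in percent (x axis, log scale); points are medians and bars run between the quartiles over genes. The slick medians go from 3.14 to 4.08 and the source medians from 2.94 to 3.51. The 7 members without a control count enter at fitted values that are no bounds, and the upper quartiles depend on them.

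At the high slick dose, 222 genes were higher and 115 lower than control among 86459 tested. TRINITY_DN113713_c1_g1, a contig of 247 bases, had no count in any control library and 5.07 ± 2.42 CPM in exposed larvae (SD, n = 3), at least 287-fold higher against a floor of 3 counts over the controls. TRINITY_DN124558_c0_g1 also had no count in controls and 2.14 ± 1.72 CPM in exposed larvae (SD, n = 3), with an edgeR adjusted p of 0.04. Of the genes that fell, TRINITY_DN10279_c1_g1 went from 3.55 ± 0.596 to 0.548 ± 0.196 CPM (SD, n = 3 each), a log2 fold change of -2.69 (SE 0.38, edgeR adjusted p = 0.00285). TRINITY_DN113952_c0_g1 went from 5.82 ± 1.72 to 1.2 ± 0.388 CPM (SD, n = 3 each), a log2 fold change of -2.27 (SE 0.43, edgeR adjusted p = 0.0276). The calls of TRINITY_DN124558_c0_g1 and TRINITY_DN113952_c0_g1 were lost without any 1 of the control libraries, with edgeR adjusted p from 0.0561 to 0.17. The second then had log2 fold changes of -2.42, -2.36 and -2, close to the full fit, and the fitted value of the first stayed between 9.95 and 9.99, which is no bound because controls had no count. The first was also lost without slick_H replicate 2 or 3 (adjusted p of 0.0904 and 0.0697), and the second without slick_H replicate 1 or 2 (0.185 and 0.144), at log2 fold changes of -2.08 and -2.21. The replicate number as a block ended both calls (adjusted p of 0.0711 and 0.0622), with the second at -2.27. The first has 1 transcript, so the refit on transcripts kept its counts, and its edgeR adjusted p there was 0.0621. On the main transcript of the second the edgeR adjusted p was 0.806, with a log2 fold change of -1.44 (SE 2.17). The count of 337 genes became 154, 134 and 161 without control replicate 1, 2 or 3, and 173 and 190 without slick_H replicate 1 or 2. The 115 lower genes among them became 35, 31 and 46, and 36 and 28, in the same order, and 43 with the replicate number as a block. Other planned settings gave up to 1877 genes in all, with DESeq2.

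The low slick dose gave 52 genes higher and 1 lower, and the middle dose 161 higher and 10 lower. The gene lower at the low dose was TRINITY_DN140104_c2_g1, with a log2 fold change of -1.07 (SE 0.17, edgeR adjusted p = 0.0218). Of the 52 genes higher at the low dose, 50 were also higher at the high dose and 48 at all 3 doses. TRINITY_DN113713_c1_g1 was called at each slick dose, with 5.15 ± 1.72 CPM at the low dose (SD, n = 3) and 4.67 ± 1.25 at the middle dose (SD, n = 2), so its level did not differ between doses beyond the spread. Its call at the middle dose was lost with only the groups compared in the fit (edgeR adjusted p = 0.106). TRINITY_DN141155_c1_g1, whose main contig has 4000 bases, rose 36.8-fold, 58.1-fold and 80.6-fold at the low, middle and high dose. Its main transcript alone had no count in controls and 0 to 95 counts in the slick libraries, with fitted log2 values of 8.1, 8.48 and 9.04 that are no bound (SE 2.92 to 3, against 0.33 to 0.35 for the gene), and was not called (edgeR adjusted p of 1, 1 and 0.357). With DESeq2 the low dose gave 183 genes higher and 32 lower. The count of 53 at the low dose became 21, 18 and 23 without control replicate 1, 2 or 3, and 29 without slick_L replicate 2. The 171 genes of the middle dose became 64, 48 and 66 without control replicate 1, 2 or 3, and 67 without slick_M replicate 1. With only the groups compared in the fit the low dose gave 15 genes and the middle dose 9.

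At the middle slick dose the largest fitted rises were in TRINITY_DN200471_c0_g1 and TRINITY_DN124558_c0_g1, which had no count in any control library. The first had 53.8 ± 72.1 CPM (SD, n = 2), from 2.87 in 1 library to 105 in the other, and the second 9.41 ± 11.9 CPM (SD, n = 2), from 0.988 to 17.8, with edgeR adjusted p of 0.00129 and 0.0148. TRINITY_DN111481_c0_g1 fell from 5.5 ± 1.51 CPM (SD, n = 3) to 1.02 ± 0.498 (SD, n = 2), a log2 fold change of -2.42 (SE 0.4, edgeR adjusted p = 0.0155). TRINITY_DN88005_c0_g1 fell from 1.62 ± 0.235 CPM (SD, n = 3) to 0.311 ± 0.0732 (SD, n = 2), a log2 fold change of -2.36 (SE 0.43, edgeR adjusted p = 0.0333). With only the groups compared in the fit none of these genes was called, with edgeR adjusted p of 0.906, 0.869, 0.547 and 0.408 in this order, and the genes that fell stayed at -2.4 and -2.34. For TRINITY_DN124558_c0_g1 and TRINITY_DN88005_c0_g1, which have 1 transcript each, the refit on main transcripts kept the same counts among more tested features. TRINITY_DN124558_c0_g1 was also lost without any 1 control library (adjusted p from 0.0826 to 0.0963), without slick_M replicate 1 (0.124), with the replicate number as a block (0.0565) and on its main transcript (0.0548). TRINITY_DN111481_c0_g1 was lost without control replicate 2 or 3 or slick_M replicate 2 (0.0619, 0.0792 and 0.221), at -2.48, -2.18 and -2.01, and on its main transcript (adjusted p of 1), at -2.2 (SE 2.37). TRINITY_DN88005_c0_g1 was lost without any 1 of the control or slick_M libraries (0.102 to 0.36), at -2.16 to -2.64, with the stricter filter (0.0531), with the block (0.1) and on its main transcript (0.276).

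At the high source dose, 172 genes were higher and 153 lower than control. TRINITY_DN113713_c1_g1 stood at 4.33 ± 0.459 CPM (SD, n = 3), at least 245-fold above the floor of the controls. TRINITY_DN141155_c1_g1 rose from 0.0594 ± 0.0317 to 6.43 ± 0.65 CPM (SD, n = 3 each), 97.8-fold, a log2 fold change of 6.61 (SE 0.34, edgeR adjusted p = 2.64e-08). TRINITY_DN111481_c0_g1 fell from 5.5 ± 1.51 to 0.894 ± 0.209 CPM (SD, n = 3 each), a log2 fold change of -2.61 (SE 0.35, edgeR adjusted p = 0.00164). TRINITY_DN88005_c0_g1 fell from 1.62 ± 0.235 to 0.292 ± 0.145 CPM (SD, n = 3 each), a log2 fold change of -2.44 (SE 0.38, edgeR adjusted p = 0.00648). The calls of both genes that fell were lost when only the control and high source libraries entered the fit, with edgeR adjusted p of 0.111 and 0.295; their log2 fold changes stayed at -2.58 (SE 0.33) and -2.4 (SE 0.43). The second of these genes has 1 transcript, so the refit on transcripts kept its counts. On main transcripts alone neither gene was called (edgeR adjusted p of 0.841 and 0.0532), at -2.72 (SE 2.08) and -2.46 (SE 0.44). Nor was TRINITY_DN141155_c1_g1 (0.403), whose main transcript had no count in controls and 165 to 190 counts in the high source libraries, a fitted log2 value of 10.56 (SE 3.04). The count of 325 became 137 and 140 without control replicate 1 or 2, 184 without source_H replicate 2 and 20 with only the groups compared in the fit. The 153 lower genes among them became 41 and 51 without control replicate 1 or 2, and 81, 61 and 75 without source_H replicate 1, 2 or 3. The balance of directions turned with DESeq2, at 608 higher and 729 lower, and without control replicate 3, at 135 higher and 182 lower. The stricter filter gave 195 and 196. Of the settings added after seeing the data, the repeated files gave 293 and 375 and the axis covariate 3531 and 3671. More genes stayed higher with RLE factors, no low-count filter, the block, transcripts and only the groups compared.

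The low source dose gave 40 genes higher and 7 lower, and the middle dose 63 higher and 12 lower. All 40 genes higher at the low dose were also higher at the high dose, and 39 were higher at all 3. TRINITY_DN113713_c1_g1 was at least 321-fold and 381-fold above the floor of the controls at these doses; its call at the middle dose was lost with only the groups compared (edgeR adjusted p = 0.0695). TRINITY_DN141155_c1_g1 rose 42.4-fold at the low dose and 52-fold at the middle dose; its main transcript alone was not called there (edgeR adjusted p of 1 and 0.817, fitted log2 values of 8.55 and 8.49, SE 2.94 and 3). At the low dose TRINITY_DN111481_c0_g1 fell from 5.5 ± 1.51 to 1.4 ± 0.243 CPM (SD, n = 3 each), a log2 fold change of -1.98 (SE 0.34, edgeR adjusted p = 0.0465). TRINITY_DN221941_c0_g1 fell from 67.3 ± 8.72 to 22.4 ± 2.13 CPM (SD, n = 3 each), a log2 fold change of -1.59 (SE 0.24, edgeR adjusted p = 0.0179). Both calls were lost without any 1 of the control or source_L libraries, the first at -1.74 to -2.13 (adjusted p from 0.106 to 0.355) and the second at -1.48 to -1.67 (0.0591 to 0.128). The first was also lost with the stricter filter (0.0639) and with the block (0.0896). Both were lost on their main transcripts (1 and 0.0998), at -1.58 (SE 2) and -1.59 (SE 0.25). The second has 1 transcript, so that refit kept its counts. At the middle dose TRINITY_DN73259_c0_g1 fell from 1.45 ± 0.211 CPM (SD, n = 3) to 0.467 ± 0.0125 (SD, n = 2), a log2 fold change of -1.63 (SE 0.29, edgeR adjusted p = 0.0479). Among the planned refits this call was kept with DESeq2 only, and the others had log2 fold changes of -1.51 to -1.72 (adjusted p from 0.0541 to 0.534). TRINITY_DN140104_c2_g1 fell there by 1.31 on the log2 scale (SE 0.2, edgeR adjusted p = 0.0137). With DESeq2, which called more genes, the balance of directions turned: 116 higher and 182 lower at the low dose, and 159 higher and 240 lower at the middle dose. The count of 47 at the low dose became 19, 17 and 19 without control replicate 1, 2 or 3, and 21 and 22 without source_L replicate 1 or 2. The 75 genes of the middle dose became 35, 29 and 38 without control replicate 1, 2 or 3, and 26 and 30 without source_M replicate 1 or 2. With only the groups compared in the fit the low dose gave 42 higher and 58 lower, and the middle dose 8 genes.

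**Figure D2:**
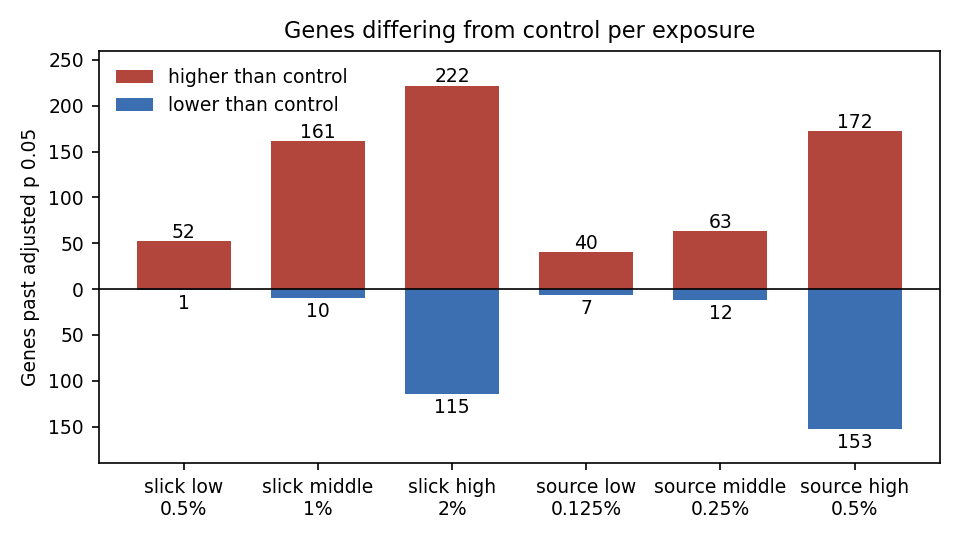
Number of genes (y axis) past an edgeR adjusted p of 0.05 against control for each oil and dose (x axis, nominal dilution in percent); bars above 0 count genes higher than control and bars below 0 genes lower. The high doses have 115 and 153 genes lower than control, against 1 and 7 at the low doses. Without 1 library the lower counts of the high doses fall as far as 28 and 41. With only the groups compared in the fit, source oil has 58 lower genes at the low dose and 2 at the high dose. Slick oil then has 1 and 316.

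The high doses of both oils shared 123 genes that were higher and 44 that were lower than control, and no gene was called in opposite directions. Independent lists of these sizes would share 0.442 and 0.204 genes. In simulations of unchanged groups with drawn controls in common, lists of the same sizes made of the genes of smallest p shared 36.5 higher genes on average (29 to 47) and 7.85 lower genes (4 to 13). Part of the excess may come from the shared controls, which were too few to split. Over 36727 genes of at least 0 log2 CPM the fold changes at the high doses had a correlation of -0.01 across genes, which are not independent replicates, against 0.5 in the simulations. On the axis along which libraries of 1 group parted most, the mean score differed from control by -82.2 at the high slick dose and by 41.1 at the high source dose. The other 8 pairs of a slick and a source dose had correlations from 0.27 to 0.72. The covariance at the high doses was -0.002, against 0.06 in the simulations, a difference of -0.063. The same-sign share was 46.2%, against 66.5% in the simulations. The simulations drew each gene on its own, so they held none of the differences between whole libraries of 1 group. With DESeq2 the high doses shared 273 higher and 230 lower genes. Shared calls came to 72 higher and 13 lower, 68 and 15, and 85 and 27 without control replicate 1, 2 or 3. They came to 98 and 13 without slick_H replicate 2, 106 and 21 without slick_H replicate 1, 97 and 21 without source_H replicate 2, 107 and 19 with the replicate number as a block, and 18 and 1 with only the groups compared in each fit.

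The oils met at 1 dilution, 0.5%, which is the low slick and the high source dose. There 3 genes differed, all higher in source oil and all among the 37. TRINITY_DN105686_c0_g1 had 45.6 ± 5.91 CPM in slick oil and 143 ± 33.4 in source oil (SD, n = 3 each), 3.13-fold more in source, a log2 difference of -1.65 (95% interval -2.02 to -1.27, edgeR adjusted p = 0.00421). TRINITY_DN119678_c0_g1 had 5.86 ± 0.244 and 13.5 ± 0.696 CPM (SD, n = 3 each), 2.3-fold more in source, a log2 difference of -1.2 (95% interval -1.48 to -0.92, edgeR adjusted p = 0.00421). The third gene had 19.9 ± 2.13 and 40.9 ± 3.08 CPM (SD, n = 3 each), 2.05-fold more in source. In control larvae the first and second of these genes stood at 20.4 ± 2.18 and 2.88 ± 0.246 CPM (SD, n = 3 each). Of the 37 genes, 27 were higher in source oil at this dilution, with a median log2 difference of -0.67 for slick against source. These were 24 of the 27 members with more than 3 control counts and 3 of the other 10. No gene was called without slick_L replicate 2 or 3 or with only these groups in the fit, where the log2 differences of the named genes stayed at -1.54, -1.7 and -1.68, and at -1.2, -1.23 and -1.23. On its main transcript alone TRINITY_DN119678_c0_g1 differed by -1.29 (SE 0.28) and was not called (edgeR adjusted p = 0.706). The single direction did not hold throughout: DESeq2 called 82 genes higher in slick and 81 higher in source, the fit without a low-count filter 5 and 6, and the fit without slick_L replicate 1 called 3 and 2.

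**Figure D3:**
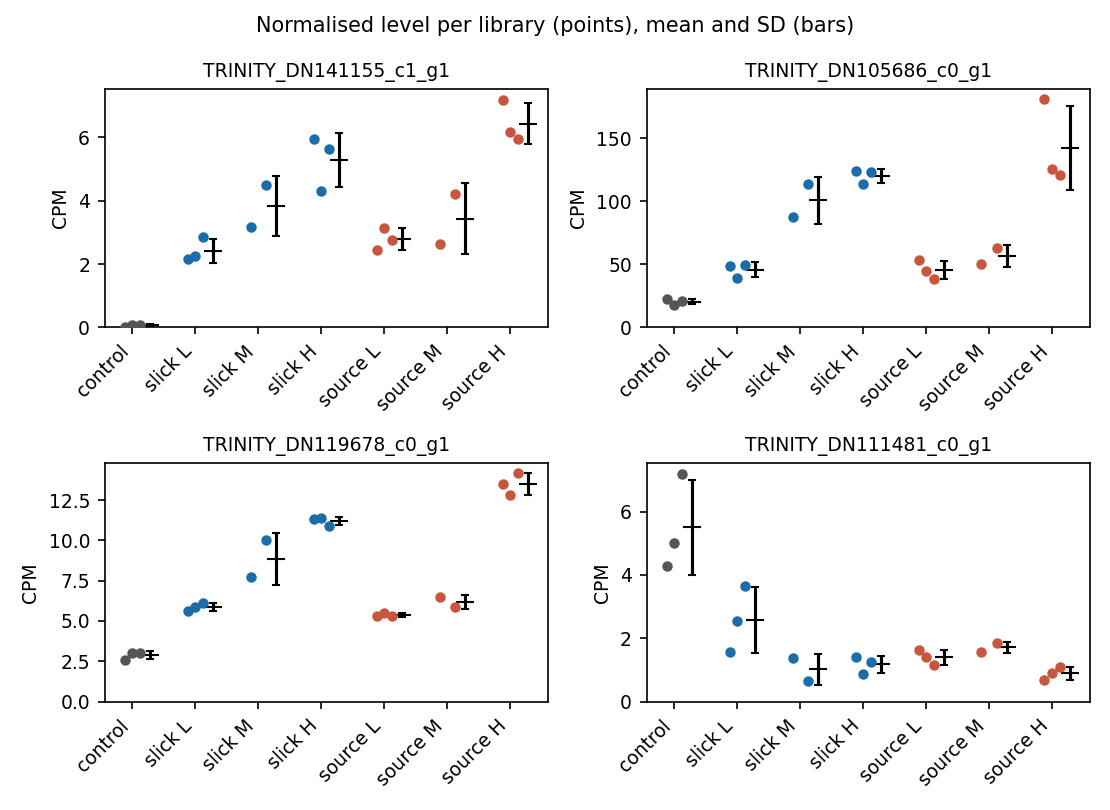
Level in CPM (y axis, linear) of 4 genes in each group (x axis, L, M and H for low, middle and high dose); points are libraries and the bars beside them give the mean and SD. TRINITY_DN105686_c0_g1 stands at 45.6 CPM at the low slick dose and 143 CPM at the high source dose, which share the dilution of 0.5%.

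At the high doses, 2% slick and 0.5% source, edgeR called no gene between oils, with 22340 genes at an unadjusted p under 0.05. DESeq2 called 4416 genes in the same libraries. Without source_H replicate 3 edgeR called 21376 genes, so 1 library decided this count. The source_H libraries then left scored 163 and 49.9 on the within-group axis, and the slick_H libraries -121.2, -76.8 and -15.4. Over the 37 genes the median log2 difference of slick against source was 0.12, with a median half-width of 0.6 for the 95% intervals. The interval, not adjusted for the number of genes, lay within 2-fold either way for 18 of the 37 genes. It excluded 0 for 9 genes higher in slick oil and 3 higher in source oil. TRINITY_DN141155_c1_g1 differed by -0.28 on the log2 scale (95% interval -0.78 to 0.22).

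The slope on the source dose was past the threshold for 103 of 78887 genes, 72 rising and 31 falling. TRINITY_DN138452_c1_g1 rose by a log2 slope of 9.4 per percent of dilution (SE 1.33, edgeR adjusted p = 0.0196), from 0.0361 ± 0.0314 CPM in control larvae to 1.15 ± 1.07 at the high source dose (SD, n = 3 each). TRINITY_DN63591_c0_g1 rose by 8.5 (SE 1.47, edgeR adjusted p = 0.0486), from 0.0657 ± 0.0429 to 1.1 ± 1.16 CPM (SD, n = 3 each). At the low and middle source doses the first gene stood at 0.106 and 0.189 CPM. The second stood at 0.0927 and 0.0904 there, so it rose at the high dose only. In source_H replicates 1, 2 and 3 the first had 99, 56 and 16 counts and the second 102, 45 and 13. These follow the order of the within-group axis scores of 163, 49.9 and -56.5. TRINITY_DN159402_c0_g1 fell by 4.13 per percent (SE 0.63, edgeR adjusted p = 0.0304), from 12.9 ± 1.8 to 2.68 ± 0.686 CPM, and TRINITY_DN182251_c0_g1 by a slope of -3.51 (SE 0.48, edgeR adjusted p = 0.0159), from 1.21 ± 0.108 to 0.348 ± 0.027 CPM (SD, n = 3 each). All 4 calls were lost without any 1 control library, with the block and on main transcripts alone (edgeR adjusted p from 0.0628 to 0.263). The slopes were then 8.59 to 9.68, 8.07 to 9.54, -3.73 to -4.13 and -3.3 to -3.52 in this order. All but TRINITY_DN138452_c1_g1 have 1 transcript, so the refit on transcripts kept their counts, among 118526 features in place of 78887. TRINITY_DN63591_c0_g1 was also lost without any 1 source_L library, source_M replicate 1 or source_H replicate 2 (0.0902 to 0.103), with dose ranks (0.0632), and without source_H replicate 1, where the slope was 5.45 (0.103). TRINITY_DN159402_c0_g1 was also lost without source_L replicate 1, source_M replicate 1 or source_H replicate 2 (0.0536, 0.0691 and 0.0731), at -4.12, -4.09 and -4.34. For slick oil edgeR called no slope among 82821 genes, with 14365 at an unadjusted p under 0.05, and DESeq2 called 1564. The slopes of the same 4 genes in slick oil were 1.12 (SE 0.49), 0.04 (SE 0.86), -0.37 (SE 0.19) and -0.88 (SE 0.17), with edgeR adjusted p of 0.27, 0.982, 0.329 and 0.163. The median source slope of all genes was 0.104 per percent. The source count became 18, 13 and 16 without control replicate 1, 2 or 3, 46, 38 and 58 without source_L replicate 1, 2 or 3, 35 without source_M replicate 1, 46 without source_H replicate 2 and 342 without source_H replicate 3. The slick count became 68 without slick_M replicate 2 and 2 without slick_H replicate 1.

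Libraries differed more within groups than the exposures explained. The first principal component held 61.9% of the variance of log2 CPM over 19 libraries, and groups accounted for 33.7% of it (permutation p = 0.462, adjusted p = 0.577 over 5 components). The second component held 9.4%, and groups accounted for 75.8% of it (permutation p = 0.00318, adjusted p = 0.00795). The score of the libraries along the first within-group axis went with the share of counts in genes under 500 bases (Pearson r = -0.95, Spearman rho = -0.95, permutation p = 1e-05 for both, the smallest that 100000 permutations give, adjusted p = 3.5e-05 over 7 relations). Without the 2 libraries farthest from the median share r was -0.93, and within groups it was -0.97.

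**Figure D4:**
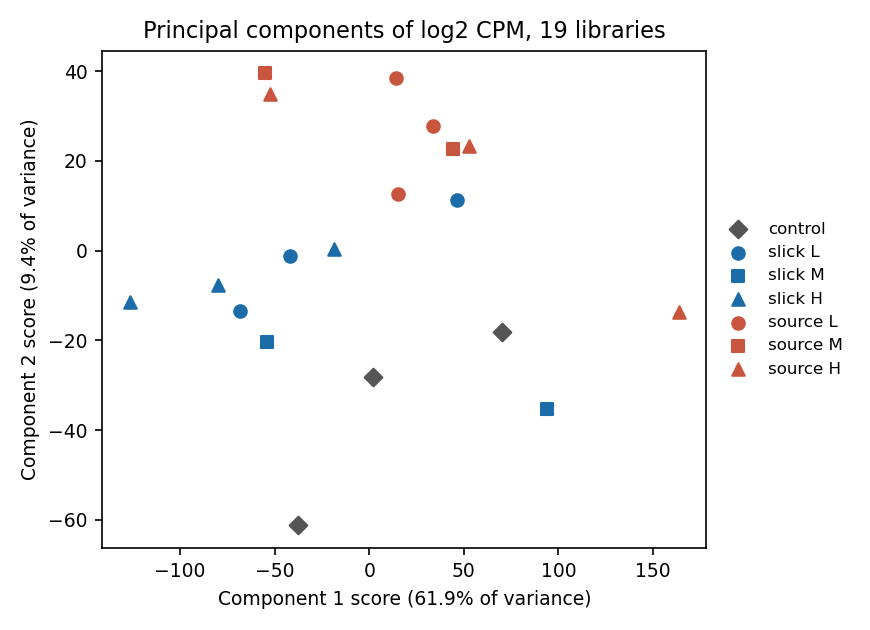
Scores of the 19 libraries on component 1 (x axis, 61.9% of the variance) and component 2 (y axis, 9.4%) of log2 CPM; each point is a library, coloured by oil and shaped by dose. Libraries of 1 group lie far apart on component 1, such as source_H at 163.6 and -52.5.

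The authors' deposited tables compared transcripts of each exposed group with control. At an adjusted p under 0.05 the authors' deposited tables listed 633 transcripts higher and 962 lower at the low slick dose, 688 and 553 at the middle dose, and 2910 and 2751 at the high dose. For source oil the authors' deposited tables listed 1255 higher and 2168 lower at the low dose, 1728 and 2802 at the middle dose, and 411 and 491 at the high dose. Of the source doses the high dose thus had the fewest, unlike the counts of genes called here. Of the 53, 171 and 337 genes called here at the low, middle and high slick dose, 25, 87 and 232 had a transcript in the authors' deposited tables and 24, 80 and 221 a called one. Of the 47, 75 and 325 genes at the source doses, 28, 50 and 256 had a transcript in the authors' deposited tables and 26, 48 and 200 a called one. The share of transcripts called in the authors' deposited tables whose gene had the same sign here ran from 77.8% at the middle slick dose to 93.9% at the low source dose.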

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

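The comparison of oils at equal dilution was planned, and the possible outcomes of removing length trends were set out before it was run; the other tests in this part were chosen after the result was seen. At the shared dilution of 0.5%, a direct test found 3 genes whose response to slick oil was smaller than to source oil. The log2 differences of slick against source were -1.65 for TRINITY_DN105686_c0_g1, -1.2 for TRINITY_DN119678_c0_g1 and -1.04 for the third gene. Of the 10 splits of these 6 libraries, 2 gave as many genes: the real one with 3, and 1 other with 12711. That other split set slick_L replicate 1 and source_H replicates 1 and 2 apart, with within-group axis scores of 48.9, 163 and 49.9. Slick_L replicates 2 and 3 and source_H replicate 3 scored -41.2, -68.7 and -56.5, so the split followed this axis. With 10 splits no share under 0.05 can be had. Nominal dilutions need not hold equal amounts of dissolved oil, which was not tested here.

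The axis on which libraries of 1 group part from each other held 70.2% of the within-group variance. Length trends as its whole cause are argued against: after removal of each library's trend over contig length the axis held 70.3%, and 91.3% of the within-group variance was left. Depth as the main cause is argued against by an r of 0.05 between score and total count (within groups -0.2). Spearman rho was 0.3, and r was 0.36 without the 2 libraries farthest from the median count. A moderate relation is not excluded with 19 libraries. A difference of group means cannot set an axis defined within groups. Whether exposure changed the spread between replicates was not tested, and neither was any other biological explanation. RNA integrity or larval stage may set the axis and stay open, since the labels give neither; the axis as a covariate, chosen after seeing the data, raised the calls at the high source dose from 325 to 7202.

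The deposited middle-dose tables called 1241 transcripts for slick and 4530 for source oil. A DESeq2 refit on transcripts with replicate 2 counted again shared 1237 and 4528 of these calls, and a refit that counted it once shared 641 and 1883. The deposited mean signals were rebuilt as weighted sums of 5 distinct libraries (largest relative residual 5.2e-15 for slick and 5.5e-15 for source). Scaled by depth, replicate 2 had 2.04 and 1.81 times the mean control weight, and replicate 1 had 1.02 and 0.92. The deposited counts for these doses are thus what 1 library entered as 2 would give, which lowers the apparent spread. No biological explanation was tested for this pattern.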

How the results depend on the processing

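Counts of genes past the threshold depended on the settings, and the cause was not tested unless stated. In the order of low, middle and high slick, then low, middle and high source, the main counts were 53, 171, 337, 47, 75 and 325. DESeq2 called 215, 382, 1877, 298, 399 and 1337 genes, 163 at equal dilution, 4416 between high doses, 1564 and 1081 for the slick and source slopes, 503 shared and 57 higher in all 6. Without a low-count filter the low and middle slick counts were 93 and 263, equal dilution 11, high doses 159, and the slopes 310 and 385. With at least 50 counts in 3 libraries the middle slick count was 98 and the slick slope 13. RLE factors kept every count within 1.5 times. Transcripts in place of genes gave 28, 52, 163, 19, 40 and 138, with 1 at equal dilution, 15 between high doses, and slopes of 1 and 18; more features were tested. Dose ranks gave slopes of 31 and 180. With only the groups compared in the fit, the spread came from those libraries alone. The counts were 15, 9, 716, 100, 8 and 20, with 0 at equal dilution, 19 shared and 5 higher in all 6. They rose at the high slick and low source dose and fell at the others, so source oil had more calls at the low than the high dose. The main count of 325 thus depended on fitting all groups together. A log2 threshold of 1 left 216 at the high source dose.

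With the replicate block the high slick count was 193 and the source slope 22. Deviations of same-numbered libraries correlated at -0.08 on average (from -0.9 to 0.76), against 0.04 for different numbers. Of 19 libraries, 4 correlated best with their own number. Since 1 axis held 70.2% of the within-group variance, this check cannot exclude a smaller effect shared by libraries of 1 number. Whether the numbers pair the samples stays open. The block moved no other total by over 1.5 times, except that the 1 gene lower in all 6 became 0. Among parts of totals it moved lower genes from 1, 10 and 115 to 0, 3 and 43 at the slick doses and from 7 to 3 at the low source dose, shared lower genes from 44 to 19, and the source slope from 72 rising and 31 falling to 17 and 5. It ended 20 of the 63 calls of named genes.

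Added after seeing the data, the repeated files as separate libraries gave 88, 354, 688, 82, 540 and 668, slopes of 8 and 166, 287 shared and 56 higher in all 6. The axis covariate gave 715, 798, 2062, 3362, 2313 and 7202, with 457 at equal dilution, 3 between high doses, slopes of 136 and 3971, 1520 shared and 144 higher in all 6.

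Leaving out 1 library at a time gave 18 to 49, 48 to 151, 134 to 334, 17 to 33, 26 to 38 and 137 to 317, with 0 to 5 at equal dilution, 0 to 21376 between high doses, 0 to 68 and 13 to 342 for the slopes, 83 to 172 shared and 14 to 42 higher in all 6. A lone library of a middle dose was assumed to vary like the other groups. Of the 37 genes, 32 remained with DESeq2, 37 with RLE factors, 33 without a low-count filter, 26 with the stricter filter, 30 with the block, 5 with only the groups compared and 14 to 16 without a control library. Over 834 refits of the 63 calls of named genes under planned settings, 590 kept the call, 244 lost it and 0 turned direction. Main transcripts lost 40 of the 63 and only the groups compared 28 of 56. Several named genes have 1 transcript, so their refits on main transcripts kept the same counts among more features. Over 126 refits under the settings added after seeing the data, 124 kept the call and 2 lost it. Both settings lower the estimated spread by construction, so these kept calls are no evidence of stability. The gene list tests were not run, because identifiers carry no names. With 2 libraries, the simulated middle slick dose recovered 13% of 2-fold changes in genes above 1 CPM in controls. The high slick dose with 3 recovered 21% of such changes. Other doses were not simulated, and depth as the limit was not tested.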

Other observations

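All tests in this part were chosen after the result was seen. A group of genes had no count in any control library while most exposed libraries held them. The criterion first looked at, 20 counts in all 16 exposed libraries, gave 1 gene, and some other sets of 3 libraries also gave 1. A looser criterion of 5 counts in at least 12 of the 16 was then picked after its count was seen, and gave 18 genes against 13 for the highest of the other 968 sets. Over a grid of 9 criteria the controls gave 1 to 18 genes and stood above every other set in 8. No gene had the reverse pattern. The results below rest on the looser criterion.

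Of these 18 genes, 7 belonged to the 37 genes higher in all exposures, and their median contig length was 363 bases against 1052 for all genes. The level in exposed libraries gives at least 27 expected counts per gene in the controls. At the depth of these controls, the criterion of 5 counts in 12 libraries itself keeps this number up. It is therefore no test of low control depth. The control libraries held 47681606 to 69271086 counts and the shallowest exposed library 26868206, so the controls were not the shallowest libraries. The genes varied together across exposed libraries within groups, with a mean correlation of 0.49 across pairs of genes, against a 95th percentile of 0.21 and a maximum of 0.43 in 1000 random lists matched on abundance and contig length. With the axis on which libraries of 1 group part taken out, it was 0.53, against a maximum of 0.22. A shared origin, such as transcripts of another organism or 1 regulated programme of the larvae, is a candidate explanation, and this test does not separate those. Their level was higher at the high than the low slick dose by a median log2 difference of 0.7 (quartiles 0.47 and 0.92), and for source oil the median was -0.23 (quartiles -0.4 and 0.01), so a rise with source dose stays undecided.

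Other splits of the 6 libraries of a comparison called no gene for the low slick dose (real count 53), the high slick dose (337), the low source dose (47) and the high source dose (325). Only 1 of the 10 splits, the real one, gave as many in each case, and 10 splits are too few for a share under 0.05. For the source slope 1 of 30 regroupings of the doses, the real one, gave 103 genes and the highest other 0. The regroupings mixed control with exposed libraries, which adds the differences between these to the spread. They therefore cannot exclude chance and do not test a graded slope. Between the high doses and for the slick slope the real count was 0, which all 10 splits and all 30 regroupings reach by construction, so these say nothing about chance. The highest other was 0 between the high doses and 6765 for the slick slope, which points to a structure of the samples.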
